A study of Drosophila melanogaster with 18 samples.

How the data were processed

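Messenger RNA was measured by sequencing in Drosophila S2 cells, an embryonic line with macrophage-like traits. The samples were wild type cells and 3 derived lines that carry a copper-inducible transgene for the transcription factor Zelda (Zld), Grainy head (Grh) or Twist (Twi). Per the labels, cells were harvested 48 h after CuSO4 was added, polyA RNA was taken, and libraries were made with a kit that does not keep strand. The 18 libraries form 9 groups of 2. Wild type cells received 0, 40, 100 or 1000 µM CuSO4. The Zld and Grh lines have an untreated and an induced group, and the Twi line has an induced group at 40 µM. The labels print the induced doses of the Zld and Grh lines as 1000 and 100 mM, whereas those of wild type are printed in µM; the numbers were matched as printed and the unit was left open.

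The deposited values are counts: whole numbers of reads per gene, 1 column per library, with no normalization. Per the submitters' processing notes, reads were aligned to the dm6 genome with HISAT2 2.1.0 and counted with featureCounts of Subread 2.0; DESeq2 is named there too, and its output was not used here. The annotation release, the strand setting and the handling of reads that overlap more than 1 gene are not stated. The deposited tables also hold a second kind of value, in the unit other than counts: the gene length in bases, which was used only to check the annotation. There are 3 tables, 1 per factor, each with 17609 genes, and the untreated wild type counts are identical in all 3. Symbols were joined through the gene identifiers, which matched for 17561 genes and left 48 without a symbol. The deposited length equals the summed exon length of the reference annotation in 99.9% of matched genes. Genes that share exonic bases with another gene are given with that overlap, because reads there cannot be assigned by strand.

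The libraries hold 10459648 to 28575923 counted reads. A floor of 3 counts corresponds to 0.105 to 0.287 CPM (counts scaled to a library of 1e6) in 1 library, and floors and counting intervals cover counting error only, since the reads carry no molecular identifiers. CPM values are scaled by library size alone and are given as mean ± SD over 2 libraries, whereas fold changes use TMM factors from edgeR. A gene with no counts in both libraries of the lower group is given as "at least" a fold, computed against 3 counts over that group; with 1 to 3 counts the ratio of CPM over the group is given with its 95% exact binomial (Clopper-Pearson) interval.

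Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr defaults, TMM, robust quasi-likelihood F test, two-sided, Benjamini-Hochberg adjustment over all genes tested). A gene was called at an adjusted p under 0.05, and a call of at least 2-fold has in addition an absolute log2 change of 1 or more. Log2 changes are given ± SE. Before the data were examined, 6 comparisons were fixed, each fitted on 6 libraries of 1 table with 3 residual degrees of freedom: induced Zld against wild type at the same number and against the uninduced line, the same for Grh, induced Twi against wild type at 40 µM, and wild type at 40 µM against untreated wild type. Also fixed were 3 differences between factor effects, fitted on all 18 libraries. Because the untreated wild type libraries turned out to be in every table, 6 comparisons were added after the data were seen: copper at 1000 and 100 µM in wild type, each uninduced line against untreated wild type, and the interaction of line and copper for Zld and for Grh. These fits hold 8 libraries and 4 residual degrees of freedom. The labels do not say whether replicates are separate cultures, so every p measures the spread between these samples. No group has 3 libraries, so neither a test for a deviating library nor a count over regrouped samples was made.

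Gene lists were written from textbook knowledge at the same early stage: 21 lists with 339 entries, of which 326 matched by symbol and 12 by an older name, and 1 repeats a gene. They cover the metal response, oxidative stress and glutathione, heat shock and chaperones, cytosolic ribosomal proteins (92 genes by symbol prefix), DNA replication and cell cycle, apoptosis and DNA damage, early zygotic patterning and cellularization, cuticle and wound response, epithelial polarity and adherens junction, septate junction, mesoderm and ventral furrow, neuroectoderm dorsoventral targets, muscle differentiation, plasmatocyte and basement membrane, lamellocyte and crystal cell, antimicrobial peptides, neuron and neuroblast, germline and ovarian soma, fat body, ecdysone response, and Enhancer of split. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01, at least 3 tested members, two-sided), with Benjamini-Hochberg adjustment over 122 tests in the 6 planned comparisons; the 120 tests in the added comparisons were adjusted among themselves. List members are counted by the genewise edgeR calls over all genes and, where it differs, adjusted over the list alone. With the correlation estimated from the data, camera called 0 of the 122 planned tests (6 had an unadjusted p under 0.05) and 0 of the 120 added tests (8 had one), and that adjusted p is given beside each call.

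The genes named follow a fixed rule. The factor genes come first. For each comparison with wild type the rule takes the 10 largest increases and decreases among called genes whose 2 groups do not overlap in CPM, whose mean is at least 5 CPM in the higher group and whose symbol is not a mere number, and in the other comparisons the 5 largest. Of each list it takes up to 4 called members, smallest adjusted p first. The direction of every gene named as risen or fallen therefore holds on the group means, and for the largest changes in 2 of 2 libraries against 2 of 2.

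Overlaps of calls between factors were tested with Fisher's exact test, two-sided, over genes tested in both, with Benjamini-Hochberg adjustment over 6 tests. Overlaps of the controls share the induced libraries and were set beside the number expected from independent calls and beside 20 simulations without an effect. Alternatives were DESeq2 1.42.0, RLE factors, library size only, no filter on low counts, a replicate block, the 2 compared groups alone, all 18 libraries, no robust option, an absolute log2 change of at least 1, and each library left out in turn, where the lone library of its group is assumed to vary like the other groups. Fits on all 8 libraries of a table and fits with untreated wild type as the control were added after the data were seen. On simulated counts at the depth and spread of the Zld table, 67.2% of 1.5-fold, 83.6% of 2-fold and 93.9% of 4-fold changes were recovered in the comparison of Zld with wild type; for Twi these were 56.7%, 64.2% and 86.4%. False calls made up 5.23% of the calls in the first, 8.24% for Grh against wild type and 11.5% for copper at 40 µM. Each comparison was simulated a single time with 200 changed genes, far fewer than were called in the data. These shares may therefore not carry over to the data.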

Results

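Read counts for 17609 genes were compared in 18 RNA sequencing libraries from Drosophila S2 cells, 2 per group in 9 groups. The groups are wild type cells with 0, 40, 100 and 1000 µM CuSO4, the Zld line untreated and induced, the Grh line untreated and induced, and the Twi line induced at 40 µM CuSO4. Copper switches on the transgene in these lines and was given to wild type cells as the control for the metal itself. Each library held between 10459648 and 28575923 counts, the fewest in replicate 1 of the untreated Zld line and the most in replicate 1 of wild type at 40 µM. Between the replicates of a group, Spearman's correlation across genes ran from 0.992 in wild type at 40 µM to 0.998 in wild type at 100 µM. Genes are not independent replicates. The spread between replicates, as chi-square per degree of freedom over counting error, ran from 2.09 in wild type at 1000 µM to 41.2 in wild type at 40 µM. The series title and design put the question of how such factors act when expressed in cells that lack them, and the comparisons below ask which mRNAs changed.

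Each line expressed its own factor gene at a high level after induction. Levels of zld (FBgn0259789, chromosome X, 19766465 to 19783548 on dm6), which encodes the zinc finger activator of the early embryonic genome, were 5357 ± 206 CPM in the induced Zld line and 1.33 ± 0.334 in wild type at 1000 µM (SD, n = 2 each). The log2 change was 12.07 ± 0.28 (adjusted p = 1.94e-08). Levels of grh (FBgn0259211, 2R, 17801132 to 17842820), a regulator of epidermal and epithelial genes, were 999 ± 20.9 CPM in the induced Grh line and 0.290 ± 0.0437 in wild type at 100 µM. The log2 change was 11.86 ± 0.15 (adjusted p = 9.14e-16). Levels of twi (FBgn0003900, 2R, 22985374 to 23048325), the bHLH factor that specifies mesoderm, were 1776 ± 256 CPM in the induced Twi line and 0.296 ± 0.0716 in wild type at 40 µM. The log2 change was 12.54 ± 0.45 (adjusted p = 3.39e-05), and 22.4% of its exonic bases also lie in other genes. Both uninduced lines already held transcripts of their factor. The uninduced Zld line had 260.3 ± 65.3 CPM of zld, and induction raised it by 4.38 ± 0.18 on the log2 scale (adjusted p = 4.75e-07). The uninduced Grh line had 40.4 ± 5.87 CPM of grh, and induction raised it by 4.68 ± 0.08 (adjusted p = 3.25e-14). At low levels twi and zld were also called in cells without their construct. Whether reads of twi were carried over between libraries was not tested. In the induced Zld line twi had 2.34 ± 0.953 CPM, 3.50 ± 0.65 above wild type on the log2 scale (adjusted p = 0.00216) and 1.90 above untreated wild type, where the call ended (adjusted p = 0.0521). Over the uninduced Zld line twi rose by 2.94 ± 0.64 (adjusted p = 0.00405). That change was 5.09 and 1.82 without replicate 1 and 2 of the uninduced line, and it was 2.47 and no longer called without replicate 2 of the induced line (adjusted p = 0.0501). In the induced Grh line twi had 19 counts against 2 in wild type, a ratio of 10.2 (95% interval 2.46 to 90.2, adjusted p = 0.0284). This call ended on all 8 libraries of the table and on all 18 libraries (adjusted p = 0.141 and 0.135), and against untreated wild type, where the change was -0.18. It also ended without replicate 1 of the induced Grh line (log2 change 1.38) or replicate 2 of its wild type (2.15). Without replicate 1 of its wild type the remaining library had no twi counts, so no fold is given. Between wild type at 40 µM and untreated wild type zld changed by -5.45 ± 1.23 (adjusted p = 0.0137), by -2.93 without replicate 1 and -6.32 without replicate 2 of the untreated cells. That call ended without the filter (adjusted p = 0.132) and without replicate 1 or 2 at 40 µM (adjusted p = 0.176 and 0.149).

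**Figure D1:**
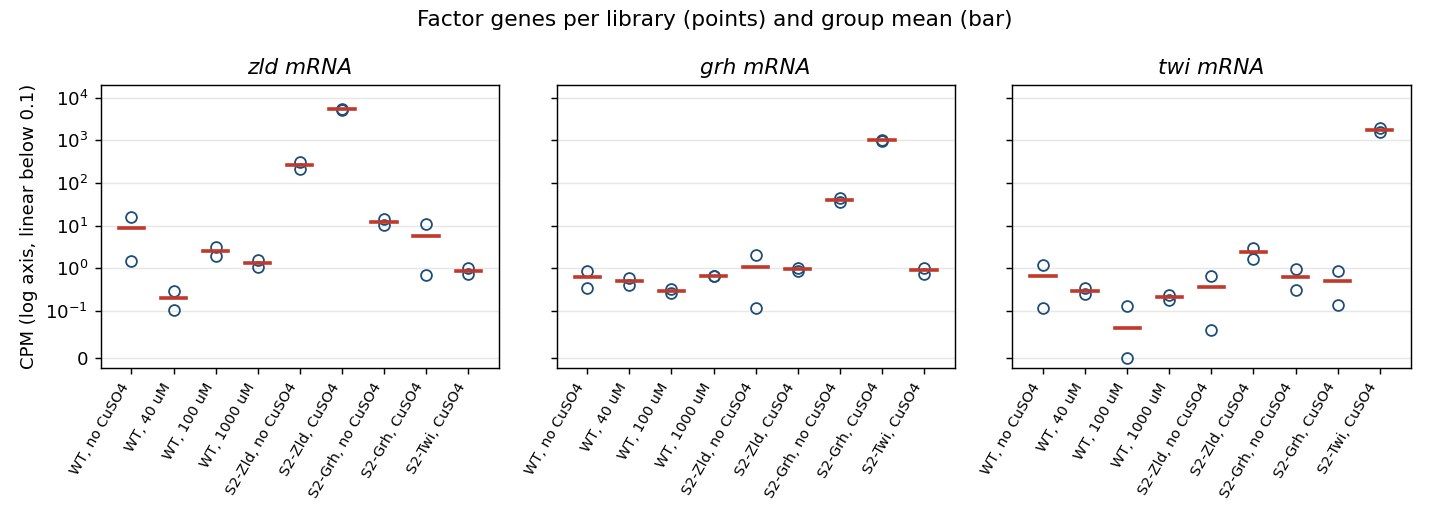
Levels of zld, grh and twi mRNA in CPM (log axis, linear below 0.1) in the 9 groups; points are libraries and bars group means (n = 2). Each gene is highest in its own induced line, and zld and grh are also present in their uninduced lines.

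In the induced Zld line against wild type at 1000 µM, sisA was among the 10 largest increases. This gene, an X-linked counter of sex determination that Zld activates in embryos, had 287 counts against 1 in wild type, a ratio of 319 (95% interval 56.7 to 12628). Dtg, named as a target of Dpp signalling, rose by 7.77 ± 0.20 on the log2 scale (100.3 ± 6.28 against 0.483 ± 0.339 CPM, adjusted p = 2.04e-09). The gene tld, which encodes the metalloprotease that frees Dpp from its inhibitor Sog, rose by 6.12 ± 0.24 (20.2 ± 0.686 against 0.303 ± 0.0873 CPM). zye rose by 7.29 ± 0.11 to 525 ± 24.7 CPM, and the odorant-binding protein gene Obp99a rose by 6.62 ± 0.15 to 143 ± 19.3 CPM. Phk-3, babos, Cyp305a1, rst and Jhbp2, which complete the 10 largest, rose by 7.52, 6.80, 6.37, 5.14 and 5.01. Genes typical of the blood-cell character of S2 cells lay among the 10 largest decreases. The scavenger receptor gene Sr-CI fell by 2.63 ± 0.13, and the hemocyte neuropeptide-like gene Nplp2 fell by 2.57 ± 0.19 (adjusted p = 2.11e-05). Alk, a receptor tyrosine kinase, fell by 3.62 ± 0.12, the arginine kinase gene Argk1 fell by 3.43 ± 0.08, and the peptide transporter gene yin fell by 3.05 ± 0.07; ATP8B, Pgant2, RhoGAP1A, Eglp4 and He complete the set. All of these genes differed in 2 of 2 libraries against 2 of 2.

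By edgeR, 1678 genes rose and 1516 fell of 8780 tested, and 562 and 135 of these changed at least 2-fold. The total of 3194 became 1585 without replicate 1 of wild type, 1522 without its replicate 2 and 1544 without replicate 1 of the induced line. It was 4975 with untreated wild type as the control. Of the cuticle and wound response list, 7 of 10 tested members rose and none fell (9 adjusted over the list alone; camera, adjusted p = 0.000404; adjusted p = 0.642 with an estimated correlation). They include the chitin synthase gene kkv, which rose by 4.60 ± 0.46, Duox, an oxidase of barrier epithelia (2.08 ± 0.15), and Cad96Ca, a receptor kinase of wound repair (1.35 ± 0.18). Plasmatocyte and basement membrane genes fell in 11 of 18 cases, with none higher (adjusted p = 0.000196; adjusted p = 0.642 with an estimated correlation). Among them Hml, the clotting protein hemolectin, fell by 1.81 ± 0.08 and the phagocytic receptor gene eater fell by 1.62 ± 0.12. Septate junction genes fell in 6 of 14 cases, with none higher (adjusted p = 0.00601; adjusted p = 0.642 with an estimated correlation); the log2 changes of Atpalpha and cora were -0.72 and -0.53. Of 21 DNA replication and cell cycle genes 13 fell and none rose (adjusted p = 0.000653; adjusted p = 0.759 with an estimated correlation), with small changes such as a fall of PCNA by 0.39 ± 0.07. Of 86 cytosolic ribosomal protein genes 74 rose, 81 adjusted over the list alone, and none fell. Their median log2 change was 0.43 (adjusted p = 6.82e-15; adjusted p = 0.743 with an estimated correlation). The same list also stood 0.20 higher in the untreated Zld line than in untreated wild type.

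The remaining lists did not pass in this comparison. Early zygotic patterning and cellularization genes rose in 4 and fell in 1 of 14 cases (camera, adjusted p = 0.201). Of mesoderm and ventral furrow genes 6 rose, such as T48 (2.54 ± 0.14), which acts in apical constriction, and 4 of the 14 tested fell (adjusted p = 0.620). The guidance gene NetA fell by 2.16 ± 0.21. Of 17 muscle differentiation genes 8 rose and 2 fell (9 and 4 adjusted over the list alone, adjusted p = 0.161), including Mlp60A, a muscle LIM protein (2.25 ± 0.25). In the lamellocyte and crystal cell list 3 of 7 rose and 1 fell (3 and 2 adjusted over the list alone, adjusted p = 0.412); peb, the zinc finger gene hindsight, rose by 3.08 ± 0.17. Oxidative stress and glutathione genes rose in 9 and fell in 8 of 25 cases (10 and 9 adjusted over the list alone, adjusted p = 0.804). Ecdysone response genes rose in 8 and fell in 4 of 15 cases (9 and 4 adjusted over the list alone, adjusted p = 0.375), with br, a regulator of metamorphosis, higher by 0.76 ± 0.09. Of 6 Enhancer of split genes 4 rose (adjusted p = 0.0599). Of 11 apoptosis and DNA damage genes 3 rose and 1 fell (adjusted p = 0.414), with the death gene hid higher by 1.27 ± 0.10. In epithelial polarity and adherens junction 4 rose and 2 fell of 14 (adjusted p = 0.651). In neuroectoderm dorsoventral targets 1 rose and 2 fell of 6 (adjusted p = 0.964). Metal response genes, with copper in both groups, gave 1 higher and 2 lower of 7 (adjusted p = 0.554). Heat shock and chaperones gave 1 and 2 of 15 (adjusted p = 0.179). Germline and ovarian soma genes rose in 3 of 9 cases (adjusted p = 0.274), and neuron and neuroblast genes in 2 of 9 (1 adjusted over the list alone, adjusted p = 0.481). Of antimicrobial peptides edgeR and DESeq2 called 0 of 4, with 2 unadjusted p under 0.05 in edgeR (camera, adjusted p = 0.607), and of fat body genes 1 of 2 rose, too few for the list test.

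Against the untreated Zld line, the same factor change came together with copper, and metal-binding genes led. MtnB had no counts in the untreated line and was at least 136-fold higher, and MtnD had 2283 counts against 1, a ratio of 2093 (375.3 to 82707). MtnA, the main metallothionein, rose by 6.02 ± 0.12 on the log2 scale (4575 ± 112 against 71.5 ± 3.91 CPM), and MtnE rose by 7.83 ± 0.17. Dtg rose here too, by 7.95 ± 0.22, and Jhbp2, with no counts in the untreated line, was at least 52.0-fold higher. Nplp2, Alk, Argk1, Sr-CI and Pgant2 were the largest decreases, with log2 changes between -2.95 and -2.53. All of these differed in 2 of 2 libraries against 2 of 2. Of 8780 genes 2023 rose and 1768 fell, 998 and 144 of them at least 2-fold, and the total of 3791 became 2380 without replicate 1 of the induced line.

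Of the metal response list 6 of 7 rose (camera, adjusted p = 3.89e-05; adjusted p = 0.642 with an estimated correlation). Oxidative stress and glutathione genes rose in 21 of 25 cases and fell in 1 (adjusted p = 2.08e-07; adjusted p = 0.739 with an estimated correlation). The glutathione transferase genes GstS1 and GstD9 rose by 2.97 ± 0.15 and 2.03 ± 0.11. Heat shock and chaperone genes rose in 9 of 15 cases, 10 adjusted over the list alone (adjusted p = 0.00601; adjusted p = 0.759 with an estimated correlation). Hsp83 rose by 0.69 ± 0.09. Apoptosis and DNA damage genes rose in 10 of 11 cases (adjusted p = 0.00377; adjusted p = 0.642 with an estimated correlation). The death gene rpr rose by 1.07 ± 0.16 and the caspase gene Drice by 0.51 ± 0.06. Metal, glutathione and heat shock genes also rose with copper alone at 1000 µM in wild type, in 6 of 7, 18 of 25 and 14 of 15 cases. Of the apoptosis genes, copper at that dose in wild type raised rpr by 0.68 and egr by 0.59 and lowered hid by 0.69. Cuticle and wound response genes rose in 7 of 10 cases (adjusted p = 0.00409; adjusted p = 0.642 with an estimated correlation). Here Cad96Ca rose by 5.71 ± 0.33 and Duox by 3.50 ± 0.18, whereas in wild type copper at 1000 µM alone raised them by 4.17 ± 0.34 and 1.14 ± 0.20. Plasmatocyte and basement membrane genes fell in 12 of 18 cases and rose in 1 (adjusted p = 0.000404; adjusted p = 0.642 with an estimated correlation). The collagen IV gene vkg fell by 1.16 ± 0.10. DNA replication and cell cycle genes fell in 16 of 21 cases and rose in 1, 18 and 2 adjusted over the list alone (adjusted p = 0.000115; adjusted p = 0.759 with an estimated correlation). The level of Mcm5, a subunit of the replicative helicase, fell by 0.76 ± 0.07. Ribosomal protein genes rose in 5 of 86 cases and fell in 1 (1 and 0 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.0595).

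Both controls gave partly shared calls for Zld. Of the genes higher against wild type, 978 (58.3%) were also higher against the untreated line, where 387 would be expected of independent calls. Of the lower genes 806 (53.2%) were lower in both, where 305 would be expected. At 2-fold or more, 428 of the 562 higher genes were higher against both controls and 50 of the 135 lower genes were lower against both. The 10 largest increases over wild type were all called against the untreated line, and so were 9 of the 10 largest decreases, the exception being He. Because both comparisons use the same induced libraries, 20 simulations without an effect were run. They gave a correlation of the log2 changes of 0.505 against 0.677 observed, and a covariance of 0.0292 against 0.604. The share of genes with the same sign in both was 66.8% in the simulations and 68.9% in the data. Of the genes called higher against both controls 383, and of the lower genes 370, also passed the test of the interaction of line and copper.

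In the induced Grh line against wild type at 100 µM, Cpr49Af and Cpr97Ea, which encode chitin-binding cuticle proteins, had no counts in wild type and were at least 178-fold and 79.7-fold higher, and Cda4, a chitin deacetylase also without counts there, was at least 90.5-fold higher. Cht2, a chitinase, rose by 9.25 ± 0.42 on the log2 scale (381 ± 65.4 against 0.690 ± 0.0606 CPM, adjusted p = 0.000168). The cuticle protein gene Cpr64Ac rose by 9.08 ± 0.23 (94.1 ± 1.20 against 0.179 ± 0.0704 CPM, adjusted p = 3.58e-12). atilla, a surface marker of lamellocytes, and Qsox2, a sulfhydryl oxidase, had no counts in wild type and were at least 375-fold and 368-fold higher. The genes ldd and C901 were at least 147-fold and 106.9-fold higher, and the serine protease gene Sp212 rose by 8.99 ± 0.24. Among the 10 largest decreases, the complement-like gene Tep1 fell by 6.98 ± 0.21 (0.192 ± 0.0775 against 29.6 ± 0.679 CPM, adjusted p = 2.14e-13). SoYb, a Tudor domain gene of the piRNA pathway, fell by 4.33 ± 0.12, the choline transporter-like gene Ctl1 fell by 3.79 ± 0.12 and RhoGAP100F fell by 3.68 ± 0.13. The log2 changes of CrzR, Agpat2, Tret1-2 and alka were -4.15, -3.88, -3.70 and -3.61, and ChT fell by 5.11 with 69.5% of its exonic bases shared with other genes. The salivary glue gene Sgs1 fell by 6.01 ± 0.43 to 0.0988 CPM from 8.87 ± 1.08, and against untreated wild type its change was -1.36 (adjusted p = 0.218). All of these differed in 2 of 2 libraries against 2 of 2. Several of the decreases have a control that itself stands apart: in wild type at 100 µM, Tep1 was 3.11 ± 0.12 and Sgs1 4.66 ± 0.36 higher than in untreated wild type.

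Of 8666 genes 2912 rose and 2356 fell, 775 and 524 of them at least 2-fold. Of 5 metal response genes tested, with copper in both groups, Ctr1B, MtnD and MtnE were called higher, by 3.06, 2.80 and 2.59. In wild type at 100 µM MtnD and MtnE were low, at 0.478 and 0.175 CPM. MtnA stood at 2025 ± 34.6 CPM, against 834 ± 93.7 in wild type at 100 µM. The metal response was thus not matched between these groups. Cuticle and wound response genes rose in 9 of 13 cases and fell in 2 (camera, adjusted p = 0.0496; adjusted p = 0.642 with an estimated correlation). Cad96Ca rose by 6.75 ± 0.30, kkv by 6.70 ± 0.34, the pigmentation gene e by 6.32 ± 0.17 and Pu, a GTP cyclohydrolase, by 3.64 ± 0.20. Some adhesion genes rose: among epithelial polarity and adherens junction genes Fas3 rose by 4.36 ± 0.23 and ed by 1.91 ± 0.07 (5 of 14 higher, 3 lower, adjusted p = 0.767). Without copper Fas3 was already 2.17 higher in the Grh line than in untreated wild type, and induction raised it by 2.84. For ed, wild type at 100 µM stood 1.47 below untreated wild type, and induction of the Grh line raised it by 0.35. Among septate junction genes Nrg rose by 4.32 ± 0.08, to 194 ± 7.40 CPM (6 of 14 higher, 4 lower, adjusted p = 0.767). Heat shock and chaperone genes rose in 12 of 15 cases and fell in 2 (adjusted p = 0.00120; adjusted p = 0.759 with an estimated correlation). Hsp68 rose by 3.04 ± 0.07. Cytosolic ribosomal protein genes rose in 82 of 85 cases and fell in 2, with a median of 0.74 (adjusted p = 1.17e-14; adjusted p = 0.739 with an estimated correlation). DNA replication and cell cycle genes rose in 15 of 21 cases and fell in 2 (adjusted p = 0.00954; adjusted p = 0.642 with an estimated correlation). All 5 neuroectoderm dorsoventral targets fell (adjusted p = 0.00144; adjusted p = 0.642 with an estimated correlation). Among them pyr, an FGF gene, fell by 1.88 ± 0.13. In wild type at 100 µM against untreated wild type these last 4 lists moved the other way. In that comparison 11 of 15 heat shock genes were lower and 3 higher, and 70 of 86 ribosomal protein genes were lower and 2 higher. Likewise 19 of 21 replication genes were lower, and 4 of 5 neuroectoderm genes were higher. Changes at least 2-fold were mostly retained against the untreated Grh line when higher, in 473 of 775 genes (61.0%), and seldom when lower, in 25 of 524 (4.77%). Of the 10 largest increases named above all were also called against that line, and of the 10 largest decreases 3 were.

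Against the untreated Grh line, atilla and cuticle protein genes were among the largest increases. Cpr76Bc had 1281 counts against 2, a ratio of 683 (189 to 5650). Cpr49Af had 498 against 1, a ratio of 531 (94.9 to 21031), and atilla had 1049 against 1, a ratio of 1119 (200.5 to 44255). obst-E, a chitin-binding protein gene, rose by 7.73 ± 0.25 and the serpin gene Spn47C by 7.23 ± 0.27. The largest decreases were small by comparison: Kah, a Snail-type factor, fell by 1.23 ± 0.10, sm, an RNA-binding protein gene, fell by 1.23 ± 0.17, and Sr-CI fell by 1.22 ± 0.18. The log2 changes of Alp4 and Mlc2 were -1.34 ± 0.17 and -1.31 ± 0.20, and their calls ended in a fit on all 18 libraries. All of these differed in 2 of 2 libraries against 2 of 2. By edgeR 1444 genes rose and 917 fell, 596 and 35 of them at least 2-fold.

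Cuticle and wound response genes rose in 10 of 13 cases and fell in 1 (camera, adjusted p = 1.11e-05; adjusted p = 0.642 with an estimated correlation). The gene kkv rose by 7.13 ± 0.37, e by 6.38 ± 0.18 and Duox by 2.73 ± 0.16. Epithelial polarity and adherens junction genes rose in 6 of 14 cases and fell in 2, 7 and 2 adjusted over the list alone (adjusted p = 0.0379; adjusted p = 0.686 with an estimated correlation). Fas3 rose by 2.84 ± 0.19, the apical determinant gene crb by 1.42 ± 0.08 and baz, the fly Par-3, by 1.02 ± 0.05. Nrg rose by 3.20 ± 0.07 and the gliotactin gene Gli by 1.14 ± 0.11 in the septate junction list, where 3 of 14 rose and 1 fell (adjusted p = 0.109). Of muscle differentiation genes 5 of 21 rose and 2 fell (adjusted p = 0.767), with the fusion genes kirre and rols higher by 3.29 ± 0.19 and 1.73 ± 0.10. Metal response genes rose in 4 of 5 cases (adjusted p = 0.0229; adjusted p = 0.642 with an estimated correlation), MtnA by 4.85 ± 0.49. Heat shock and chaperone genes rose in 9 of 15 cases, 11 adjusted over the list alone (adjusted p = 0.00644; adjusted p = 0.805 with an estimated correlation). DNA replication and cell cycle genes fell in 11 of 21 cases, 13 adjusted over the list alone, with none higher (adjusted p = 2.01e-05; adjusted p = 0.642 with an estimated correlation). The level of polo, a mitotic kinase gene, fell by 0.27 ± 0.05. Ribosomal protein genes passed the list test with a median of 0.09 while edgeR called 2 of 85 over all genes and 0 over the list alone, and 8 had an unadjusted p under 0.05 (adjusted p = 0.0294; adjusted p = 0.842 with an estimated correlation). Against both controls, 1058 genes were higher where 485 would be expected of independent calls, and 537 lower where 249 would be. Simulations without an effect gave a correlation of 0.526 against 0.758 observed, a covariance of 0.0295 against 1.04, and the same sign in 67.5% of genes, more than the 64.0% observed. Of the shared calls 830 and 452 also passed the interaction test.

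The induced Twi line was set against wild type at 40 µM. It has no untreated group, so effects of Twi and standing differences between this line and wild type cannot be told apart. The untreated Zld and Grh lines differed from untreated wild type in 1837 and 2080 genes. Both already held transcripts of their factor, so these counts may include its effects. htl, the FGF receptor gene that Twi activates in embryonic mesoderm, rose by 10.31 ± 0.41 on the log2 scale (139 ± 21.7 against 0.0875 ± 0.124 CPM, adjusted p = 4.29e-05). SerT, the serotonin transporter gene, rose by 10.22 ± 0.32, alphaTub85E, a tubulin of testis and muscle, by 9.92 ± 0.29 and nvy, a transcriptional cofactor gene, by 6.61 ± 0.29. wrapper, an immunoglobulin domain gene of midline glia, had no counts in wild type and was at least 89.3-fold higher. The genes Timp and CCHa2-R had 2 counts each, with ratios of 208 (57.2 to 1724) and 168 (46.0 to 1392). For Timp 15.7% of the exonic bases lie in other genes. GstE1, Best2 and SP1173 rose by 6.66, 6.52 and 6.07. Among the decreases, sli, the ligand of Robo receptors, fell by 2.55 ± 0.13 (173 ± 10.7 against 994 ± 177 CPM, adjusted p = 6.59e-05), and Hml fell by 2.88 ± 0.19. The level of yin dropped from 535 ± 76.8 to 67.7 ± 6.29 CPM, and the odorant receptor gene Or85d fell by 4.86 ± 0.39. The log2 changes of ec, out, Itgbn and Ten-a were -2.68, -2.54, -2.43 and -2.24. Esp fell by 3.96, and its call ended without the filter on low counts. Fas3 fell by 3.20 ± 0.27, but it was 5.03 ± 0.33 higher in wild type at 40 µM than in untreated wild type, and Twi cells stood 1.83 above the latter. All of these genes differed in 2 of 2 libraries against 2 of 2.

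Of 8909 genes 557 rose and 380 fell, 353 and 130 of them at least 2-fold. The replicate differences of these 2 groups correlated at 0.61 across 6708 genes, and this fit leaves them in its spread. The total of 937 was 424 without replicate 1 of the Twi line, 471 without its replicate 2, 554 on the compared groups alone, 1419 without the filter, 1945 on all 18 libraries and 4307 against untreated wild type. In the mesoderm and ventral furrow list 5 of 15 rose and 3 fell, 5 and 5 adjusted over the list alone (camera, adjusted p = 0.742). There if, the integrin alpha chain of muscle attachment, rose by 4.64 ± 0.28, T48 by 2.80 ± 0.22 and how by 1.13 ± 0.08. Of 18 muscle differentiation genes 5 rose and 3 fell, 5 and 4 adjusted over the list alone (adjusted p = 0.530). The actin gene Act87E rose by 4.12 ± 0.31, Mlp60A by 3.72 ± 0.33 and kirre by 3.56 ± 0.30, and blow, a fusion gene, fell by 0.64 ± 0.08. Fat body genes rose in 3 of 4 cases (adjusted p = 0.00216; adjusted p = 0.642 with an estimated correlation), Lsp1gamma, a larval storage protein gene, by 5.53 ± 0.36. Septate junction genes fell in 10 of 14 cases, with 2 higher adjusted over the list alone (adjusted p = 0.000404; adjusted p = 0.642 with an estimated correlation). The log2 changes of Lac and cora were -0.85 ± 0.09 and -0.55 ± 0.07. In wild type at 40 µM 9 of these 14 genes stood above untreated wild type and 2 below. Cuticle and wound response genes rose in 2 of 8 cases, 4 adjusted over the list alone (adjusted p = 0.0294; adjusted p = 0.687 with an estimated correlation), with Pu higher by 3.25 ± 0.38. Enhancer of split genes fell in 2 of 4, 3 adjusted over the list alone (adjusted p = 0.0136; adjusted p = 0.642 with an estimated correlation). Ribosomal protein genes passed the list test with a median of -0.08 although edgeR called 0 of 86, with 11 unadjusted p under 0.05 and 1 call by DESeq2 (adjusted p = 0.00848; adjusted p = 0.827 with an estimated correlation).

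**Figure D2:**
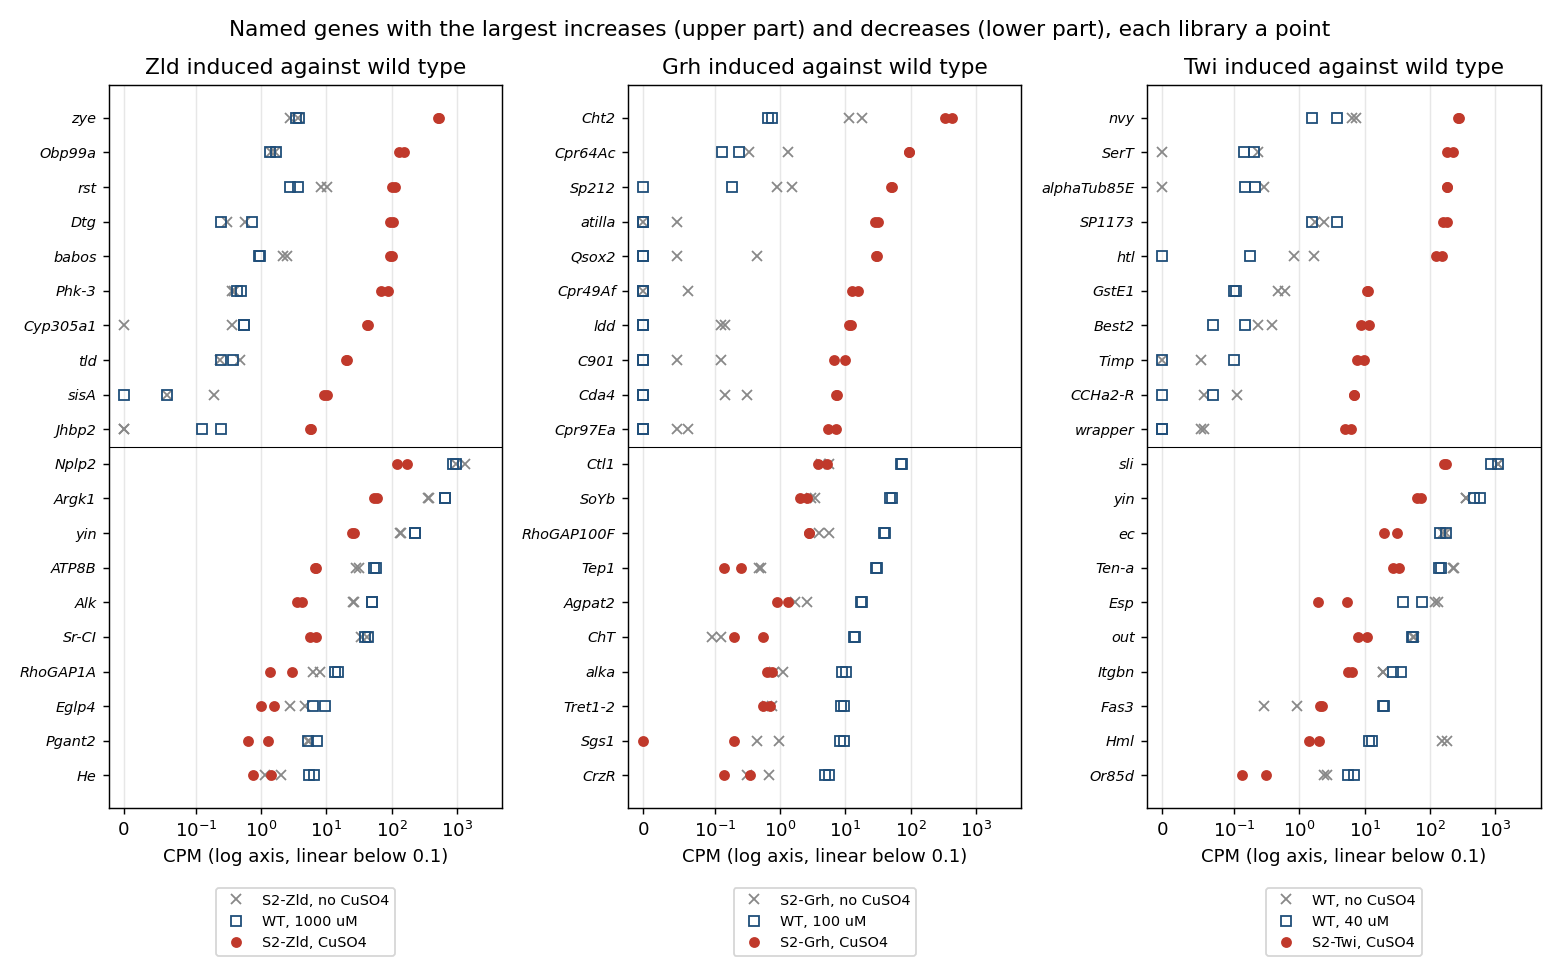
Level in CPM (log axis, linear below 0.1) of the named genes with the largest increases and decreases. Each panel shows an induced line, its wild type control and the untreated line, or untreated wild type for Twi. Each point is a library (n = 2 per group). The induced line and its wild type control do not overlap for any gene, because the naming rule required it.

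**Figure D3:**
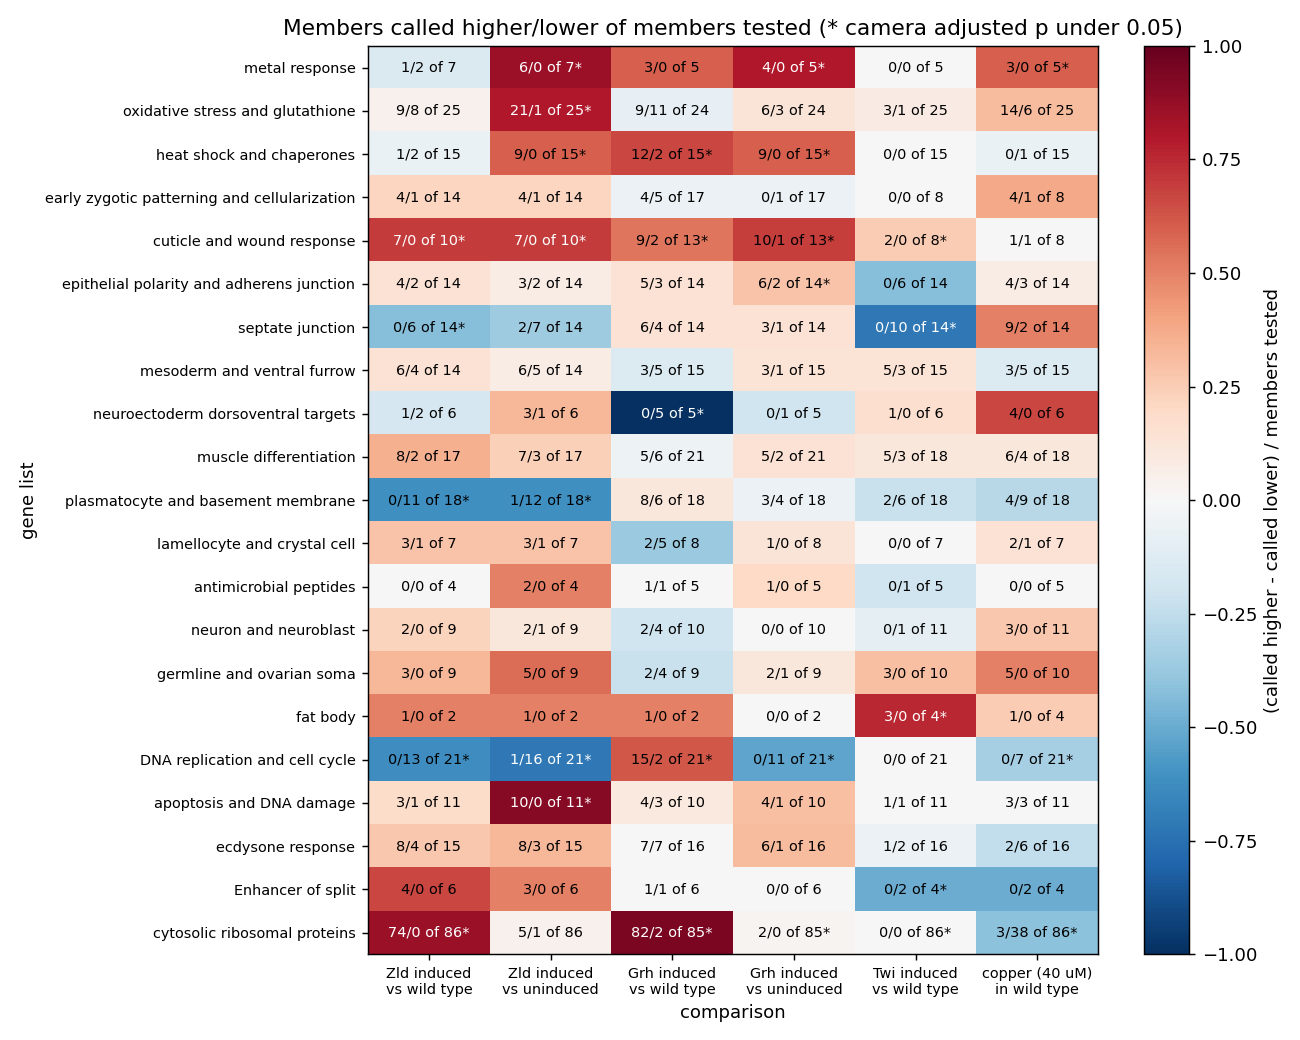
Fixed gene lists by comparison: each cell gives the members called higher and lower of those tested, the colour the difference of these counts as a share of the members tested, and a star a camera adjusted p under 0.05. With an estimated correlation no list in the 6 planned comparisons would carry a star.

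Wild type cells at 40 µM differed from untreated ones in many genes besides metal genes. Sgs1 rose by 7.68 ± 0.20 (67.9 ± 8.07 against 0.332 ± 0.141 CPM, adjusted p = 6.07e-06), eIF3f2, a translation initiation factor gene, by 4.57 ± 0.22, the trehalose transporter gene Tret1-2 by 4.05 ± 0.30 and Gs2, a glutamine synthetase, by 4.07 ± 0.69. The call of Gs2 ended without the filter and without replicate 1 of untreated wild type (adjusted p = 0.0647 and 0.0567). Had2, Tbh, Eglp4, slam and Sr-CI were the largest decreases, and Sr-CI fell by 5.25 ± 0.19 to 1.39 ± 0.338 CPM. These differed in 2 of 2 libraries against 2 of 2. MtnD had no counts without copper and was at least 15.6-fold higher, and MtnA rose by 3.28 ± 0.37. Metal response genes rose in 3 of 5 cases (camera, adjusted p = 0.0229; adjusted p = 0.642 with an estimated correlation). Glutathione genes rose in 14 and fell in 6 of 25 cases (adjusted p = 0.0909), with GstD9 higher by 2.11 ± 0.18. Ribosomal protein genes fell in 38 of 86 cases and rose in 3, 41 and 3 adjusted over the list alone (adjusted p = 1.87e-05; adjusted p = 0.759 with an estimated correlation). Replication genes fell in 7 of 21 cases, 11 adjusted over the list alone (adjusted p = 0.00954; adjusted p = 0.827 with an estimated correlation). Hml fell by 3.73 ± 0.14, while AGO3, a piRNA pathway gene, rose by 2.99 ± 0.10. Of 8909 genes 1857 rose and 1754 fell, 724 and 355 of them at least 2-fold. The total of 3611 was 1516 without replicate 1 and 1452 without replicate 2 of untreated wild type.

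At 1000 µM the response was led by metal genes. MtnD had no counts without copper and was at least 1047-fold higher. MtnB had 313 counts against 1, a ratio of 338 (60.2 to 13396), and MtnA rose by 6.48 ± 0.43. The log2 changes of Tdh, Nepl4, GstO1 and Ctl1 were -3.08, -2.21, -2.02 and -1.94. The glutathione transferase gene GstD6 rose by 3.44 ± 0.27. All of these changed in 2 of 2 libraries. Metal response genes rose in 6 of 7 cases (camera, adjusted p = 2.25e-07; adjusted p = 0.540 with an estimated correlation). Glutathione genes rose in 18 of 25 cases, 20 adjusted over the list alone (adjusted p = 1.63e-09; adjusted p = 0.852 with an estimated correlation). Heat shock genes rose in 14 of 15 cases (adjusted p = 8.84e-07; adjusted p = 0.852 with an estimated correlation). No member of these 3 lists fell. At 100 µM CBP rose by 3.81 ± 0.12 and Sgs1 by 4.66 ± 0.36, Eglp4 fell by 6.93 ± 0.34 and the potassium channel gene eag fell by 4.57 ± 0.18. MtnA stood at 89.3 ± 52.4, 836 ± 24.0, 834 ± 93.7 and 7869 ± 589 CPM with 0, 40, 100 and 1000 µM (n = 2 each). At 1000 µM 1363 genes rose and 1231 fell of 8881. The total of 2594 was 1227 and 1229 without replicate 1 and 2 at 1000 µM, 1388 and 1390 without replicate 1 and 2 of untreated wild type, and 3897 on the compared groups alone. At 100 µM 2234 rose and 2377 fell of 8788. Across genes, Spearman's correlation of group means with untreated wild type was 0.947 at 40 µM, 0.970 at 100 µM and 0.983 at 1000 µM, and the groups at 40 and 100 µM correlated with each other at 0.976.

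**Figure D4:**
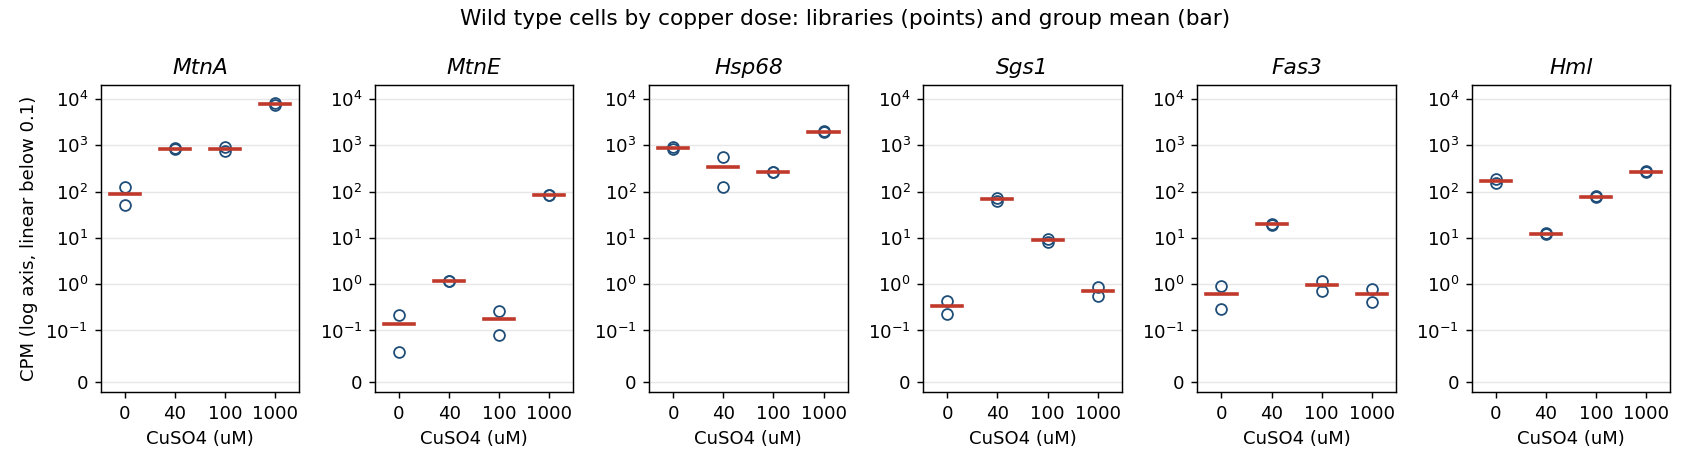
Levels of MtnA, MtnE, Hsp68, Sgs1, Fas3 and Hml in wild type cells in CPM (log axis, linear below 0.1) by CuSO4 dose in µM; points are libraries and bars group means (n = 2). MtnA climbs from 89.3 to 7869 CPM.

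Without copper the lines differed from wild type. Because both lines already held transcripts of their factor, such differences may include its effects. Oatp33Ea, an organic anion transporter gene, was 5.95 ± 0.23 higher on the log2 scale in the Zld line (21.7 against 0.367 CPM) and 7.23 ± 0.15 higher in the Grh line (52.0 against 0.367 CPM). In the Grh line goe and l(3)neo38 were 6.51 ± 0.37 and 5.19 ± 0.18 higher, and the log2 differences of SoYb and Agpat2 were -3.69 ± 0.11 and -4.12 ± 0.14. In the Zld line those of the cytokine gene upd2 and of Agpat2 were -2.22 and -1.99. These genes differed in 2 of 2 libraries against 2 of 2. Ribosomal protein genes were higher in 29 of 86 cases in the Zld line, 44 adjusted over the list alone with 1 lower (camera, adjusted p = 2.01e-09; adjusted p = 0.852 with an estimated correlation). In the Grh line 69 were higher and 2 lower, 77 and 3 adjusted over the list alone (adjusted p = 1.14e-17; adjusted p = 0.852 with an estimated correlation). Germline genes fell in 5 of 9 cases in the Grh line (adjusted p = 0.00695; adjusted p = 0.852 with an estimated correlation). The Zld line had 927 genes higher and 910 lower. The total of 1837 was 782 and 818 without replicate 1 and 2 of untreated wild type and 927 on the compared groups alone. The Grh line had 1029 higher and 1051 lower. The total of 2080 was 1375 without replicate 1 of untreated wild type and 1184 on all 18 libraries. Genes at least 2-fold changed after induction against wild type were looked up among the calls of any size without copper. Of the lower genes, 58 of 135 (43.0%) in the Zld line and 190 of 524 (36.3%) in the Grh line were already lower. Independent calls would give 13.9 and 61.3. Of the higher genes, 81 of 562 (14.4%) and 134 of 775 (17.3%) were already higher, where independent calls would give 59.3 and 92.0.

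Some genes differed from their own wild type control in more than 1 induced line. These overlaps may also hold differences between the lines and wild type that are present without copper, and those of the wild type controls. Of the genes that rose in both induced lines of a pair against their own wild type, Zld and Twi shared 159 where 84.9 were expected (odds ratio 2.48, Fisher's exact test, adjusted p = 9.85e-17). Grh and Twi shared 177 against 147 (1.36, adjusted p = 0.00463) and Zld and Grh 527 against 486 (1.16, adjusted p = 0.0185). Of falling genes Zld and Twi shared 134 against 65.2 (2.83, adjusted p = 1.17e-17) and Grh and Twi 117 against 103 (1.21, adjusted p = 0.109). Zld and Grh shared 381 against 419, fewer than expected (0.855, adjusted p = 0.0205). Among changes of at least 2-fold all 6 overlaps exceeded expectation, with adjusted p between 2.52e-45 and 1.08e-07. The odds ratios were then 6.24, 6.53 and 7.15 for rising genes in the order above and 29.2, 4.11 and 5.995 for falling genes, so that the last one changed sides; it was 1.19 with DESeq2. At least 2-fold in all 3 induced lines 17 genes rose and 7 fell. The former include tld, Pu, Cht2, babos and Cyp305a1 and the latter Hml, eater, NetA and Argk1. These names were picked after their values were seen. In the untreated Grh line Cht2 was already 4.55 higher than in untreated wild type, whereas Pu was 0.25 higher and not called. Also among the 17 is twi, the transgene of the Twi line. Without copper NetA was already 1.82 lower in the Zld line and 1.85 lower in the Grh line than in untreated wild type. Its changes on induction were -0.57 (edgeR, adjusted p = 0.101, not called) and -0.69. Hml was already 2.09 lower in the untreated Grh line and fell by 0.81 on induction. In the untreated Zld line Hml was 0.28 and Argk1 1.08 lower, and induction lowered them by 0.86 and 2.66. The changes of the induced lines from their own wild type were also tested against each other in 1 fit of 18 libraries and 9521 genes. Such differences also hold those between the lines without copper and those between the wild type controls. Between Zld and Grh 4059 genes differed, between Zld and Twi 2011 (1304 without replicate 2 of wild type at 1000 µM), and between Grh and Twi 3820. Of the genes at least 2-fold higher with a factor, 150 of 562 (26.7%) differed from both other factors for Zld, 368 of 775 (47.5%) for Grh and 173 of 353 (49.0%) for Twi. Of the genes at least 2-fold lower these were 49 of 135 (36.3%), 360 of 524 (68.7%) and 66 of 130 (50.8%). For Grh these shares rest on wild type at 100 µM as the control, and 25 of the 524 (4.77%) were also at least 2-fold lower against the untreated Grh line. For Twi no untreated group exists, so the shares do not tell the factor from the line.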

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

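Among the tests in this part, those of the interaction of line and copper, and those that ask whether Grh induction or a line difference explains the ribosomal result, were chosen after the results were seen. Many genes differed between the 3 induced lines in their change from the wild type control. Each value here is listed because a test of the difference between 2 effects passed (edgeR, adjusted p under 0.05). In the fit of 18 libraries the change from wild type differed in 4059 genes between Zld and Grh, in 2011 between Zld and Twi, and in 3820 between Grh and Twi. These totals are not responses to the factors alone. They also hold differences between the wild type controls and line differences present without copper, called in 1837 genes for Zld and 2080 for Grh. Those line differences may include effects of the factor, since both untreated lines already held its transcripts. As log2 effect of Zld minus that of Grh, the protease gene Sp212 stood at -10.81 ± 0.96 and Eglp4 at -8.83 ± 0.66, while Tep1, Sgs1 and zye stood at 8.40 ± 0.34, 7.78 ± 0.59 and 6.78 ± 0.53. Of these genes Tep1, Sgs1 and Eglp4 are also far from untreated wild type in the control of the Grh line, so their differences carry that of the control. Relative to Twi, genes raised by Zld stood higher: zye (8.03 ± 0.34), Dtg (7.20 ± 0.71), Phk-3 (6.72 ± 0.68) and Obp99a (6.61 ± 1.05). In the other direction lay GstE1 (-7.55 ± 0.77), htl (-7.59 ± 0.86), SerT (-9.09 ± 1.30) and alphaTub85E (-10.45 ± 0.77). Grh minus Twi gave 9.32 ± 1.14 for the cuticle gene Cpr64Ac, -9.52 ± 1.63 for htl and -10.33 ± 1.01 for alphaTub85E. The naming rule gave 30 genes in these tests; 14 of them, with a group at or under 3 counts, are not given.

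Some genes changed by a different amount on induction of a line than with copper in wild type cells. For Zld the interaction of line and copper passed in 1110 of 8881 genes, 529 of them higher and 581 lower. That count was 593 and 622 without replicate 1 and 2 of wild type at 1000 µM, 644 and 716 without replicate 1 and 2 of untreated wild type, 699 without replicate 1 of the induced line and 2000 without replicate 2 of the untreated line. For Grh it passed in 3809 of 8788 genes, 2119 higher and 1690 lower, and in 3127 to 3947 with any 1 library left out.

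The Grh interaction rests on wild type cells that stand apart: those at 40 and 100 µM differed more from untreated wild type (Spearman's correlation 0.947 and 0.970) than those at 1000 µM (0.983). Copper at 100 µM should then have moved the same 762 genes when the Grh line was induced at that number, but their median change there was 0.00776 of that in wild type (95% bootstrap interval -0.0299 to 0.0472), which argues against copper at this dose as a cause common to both cell lines. Copper at any dose met the same objection in the Zld line, with a ratio of 0.0534 (-0.0202 to 0.109, 719 genes). Wild type cells or libraries of another batch could remain: the change from 1000 to 100 µM and the change from 0 to 40 µM, which have no library in common, correlated at r = 0.467 across 6708 genes, between the bounds of 0.5 and 0.1 set in advance for and against. By the same correlation, the induced Twi line at 40 µM stood at 0.971 with wild type at 40 µM and 0.921 with untreated wild type. Wild type at 100 µM stood at 0.977 with the untreated Zld line and 0.970 with untreated wild type. The shift was thus not seen in wild type cells alone. Another batch and a copper response of only some cells cannot be told apart. Each dose of wild type is a single group, and the labels give no batch.

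Ribosomal protein genes were higher in both induced lines than in wild type, with median log2 changes of 0.43 for Zld and 0.74 for Grh. The TMM factors do not account for the rise, since without scaling factors the Grh median was still 0.57 and 82 of 85 genes were above 0. Dropping them moved the median of all genes only from 0.049 to -0.12, so this check could not have removed the rise. Whether scaling by library size itself adds to it was not tested. For Grh, induction with its copper is argued against as the main cause. The median against the uninduced line was 0.0898, with quartiles of 0.0658 and 0.122. The interaction, which subtracts the change in wild type at 100 µM, had a median of 0.41, with 67 of 86 genes higher and 1 lower. An effect of Grh apart from copper thus stays open. Induction of Zld was not weighed: its median against the uninduced line was 0.117, with quartiles of 0.0278 and 0.165. A difference between the lines that precedes copper is in line with the median of 0.31 between the untreated Grh line and untreated wild type, where 69 of 86 genes were called higher. Whether it may lie in the cells, in the grh transcripts already there without copper, or in the libraries was not tested. The control adds to it, because ribosomal protein genes had a median change of -0.34 in wild type at 100 µM.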

How the results depend on the processing

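Fits on all 8 libraries of a table, fits against untreated wild type, and all alternatives of the added comparisons were chosen after the data were seen. The 201 results for single named genes were recomputed 2642 times: 2624 values had the same direction and side of the threshold, 16 had the same direction but were no longer called, and 2 changed direction. Those 2 are Fas3 in the Twi line and twi in the Grh line, whose changes became 1.83 and -0.18 against untreated wild type: Fas3 differs between the 2 controls, and twi had 0.652 CPM in untreated wild type in place of 0.0647 at 100 µM. The counts of calls in the 15 comparisons all stayed within 1.5 times of their value with DESeq2, RLE factors, a replicate block and no robust option.

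Counts at a log2 change of at least 1 are smaller by construction: 697 and 1142 for Zld against wild type and the uninduced line, 1299 and 631 for Grh, 483 for Twi, 1079, 802 and 486 for copper at 40, 100 and 1000 µM, 236 and 393 for the uninduced Zld and Grh lines, 357 and 1020 for the interactions, and 1483 (Zld and Grh), 689 (Zld and Twi) and 1435 (Grh and Twi) for the differences. Shared calls of the 2 controls were then 478 for Zld and 498 for Grh, and 1178 for Zld with DESeq2. Against untreated wild type 4975 genes were called for Zld and 4307 for Twi. Without the filter 1419 were called for Twi. On the compared groups alone there were 554 for Twi, 3897 for copper at 1000 µM and 927 for the uninduced Zld line, and on all 18 libraries 1945 for Twi and 1184 for the uninduced Grh line. The cause was not tested.

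With 1 library left out, and so fewer samples, the counts ranged from 1522 to 2227 for Zld against wild type, 2380 to 4288 for Zld against the uninduced line, 424 to 1258 for Twi, 1452 to 4241 for copper at 40 µM, 1227 to 1390 at 1000 µM, 782 to 2729 for the uninduced Zld line, 1375 to 1541 for the uninduced Grh line, 593 to 2000 for the Zld interaction and 1304 to 2804 for the difference of Zld and Twi. The libraries that move these counts by over 1.5 times are named beside each count above.

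The shared decreases of Zld and Grh changed sides: the odds ratio was 0.855, 5.995 at a log2 change of at least 1, 1.19 with DESeq2 and 0.905, no longer past the threshold, with the replicate block. For shared increases of Grh and Twi it was 1.13, not past the threshold, with the block, and for their shared decreases 4.11 at a log2 change of at least 1, 1.53 with DESeq2 and 1.40 with the block, each past the threshold. The cause was not tested. Of 122 list tests camera passed 31 (31 with RLE factors, 32 with the block, 30 of them shared), fry 62 (27 shared), and camera with an estimated correlation 0 (6 at an unadjusted p under 0.05). With the block the cuticle list ended its call for Grh against wild type (adjusted p = 0.0580), the neuroectoderm list gained one for Twi (adjusted p = 0.0405), and twi in the Grh line was no longer called (adjusted p = 0.0530). Replicate numbers were not taken to pair the libraries, since the labels do not say that they do. Correlations of replicate differences between groups ran from -0.28 to 0.61. The highest was that of Twi and wild type at 40 µM, where the block gave 1404 calls in place of 937. For this pair the main fit leaves a shared replicate difference in its spread.

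With library size only, the median of all genes shifted to -0.12 for Grh against wild type and to -0.10 for each uninduced line against wild type, and the share of higher calls went from 52.5% to 35.0% for Zld against wild type, 55.3% to 34.8% for Grh against wild type, 61.2% to 50.6% for Grh against the uninduced line, 50.5% to 23.5% for the uninduced Zld line and 49.5% to 20.8% for the uninduced Grh line. Depth and spread limit small changes: for the difference of Zld and Grh, 29.9% of simulated 1.5-fold, 62.7% of 2-fold and 80.3% of 4-fold changes were recovered.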

Other observations

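All tests of this part were chosen after the results were seen. Where the response of a line to copper differed from that of wild type, several gene lists passed. For Zld, plasmatocyte and basement membrane genes were lower in 9 of 18 cases by the interaction in edgeR, 14 lower and 1 higher adjusted over the list alone (camera, adjusted p = 6.39e-08; adjusted p = 0.540 with an estimated correlation). Cuticle and wound response genes were higher in 2 of 10 cases, 4 adjusted over the list alone (adjusted p = 0.0017; adjusted p = 0.540 with an estimated correlation), and germline genes in 2 of 10, 3 adjusted over the list alone (adjusted p = 0.0374; adjusted p = 0.651 with an estimated correlation). DNA replication genes were lower in 6 of 21 cases, 9 adjusted over the list alone (adjusted p = 4.01e-05; adjusted p = 0.852 with an estimated correlation). Septate junction genes were lower in 2 of 14, 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.00228; adjusted p = 0.651 with an estimated correlation). Heat shock genes were lower in 1 of 15 cases (adjusted p = 0.0403; adjusted p = 0.852 with an estimated correlation). Ribosomal protein genes were higher in 4 of 86 cases, 1 adjusted over the list alone, with a median of 0.23 (adjusted p = 2.25e-07; adjusted p = 0.852 with an estimated correlation).

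For Grh, the interaction was positive for cuticle and wound response genes in 8 of 13 cases and negative in 2 (camera, adjusted p = 0.0247; adjusted p = 0.651 with an estimated correlation). For heat shock genes, of which 11 of 15 were lower in wild type at 100 µM than in untreated wild type, it was positive in 11 of 15 cases and negative in 1, 12 and 1 adjusted over the list alone (adjusted p = 0.000881; adjusted p = 0.852 with an estimated correlation). For DNA replication genes it was positive in 13 of 21 cases and negative in 1, 13 and 2 adjusted over the list alone (adjusted p = 0.0198; adjusted p = 0.651 with an estimated correlation). For ribosomal protein genes it was positive in 67 of 86 cases and negative in 1, 70 and 1 adjusted over the list alone, with a median of 0.41 (adjusted p = 5.85e-09; adjusted p = 0.852 with an estimated correlation). For neuroectoderm genes it was negative in 4 of 5 cases (adjusted p = 0.00287; adjusted p = 0.540 with an estimated correlation).

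Transcripts of zld also appeared, unevenly, in libraries of cells without a Zld construct. Levels were 16.0 against 1.51 CPM in replicates 1 and 2 of untreated wild type, and 10.7 against 0.688 CPM in those of the induced Grh line. The uninduced Grh line had 12.3 ± 3.15 CPM. Counts of twi were uneven in the same replicates, 22 against 2 in untreated wild type and 17 against 2 in the induced Grh line. The Zld line, with 2.34 CPM of twi induced and 0.364 uninduced, holds too little to supply these at the shares below. Counts of grh were 21 against 2 in replicates 1 and 2 of the uninduced Zld line and 16 against 6 in untreated wild type. In the induced Zld line they were 14 in each. Sources other than the Zld line were not tested. The tests ask whether other genes of the Zld line came along, and the present form, with its rule, is the 4th and was chosen with its values known: the 3 earlier forms summed the excess of those genes and favoured the uninduced Zld line as a source, the last with 114.9 CPM over random lists in untreated wild type (predicted 147, SD 47.2) and 109 CPM in the Grh line (predicted 84.5, SD 67.2). By the median share of the source that each gene needs, reads carried over from the induced Zld libraries stay open, with 0.0230% (95% bootstrap interval 0 to 1.28%) in untreated wild type, where zld needs 0.2503%, and 0.656% (0.0188 to 2.20%) in the Grh line, where zld needs 0.193% and a looser rule, an interval above 0, would have favoured this source. For reads or cells from the uninduced Zld line, the share in untreated wild type was -0.832% (-3.77 to 2.30%) where zld needs at least 4.28%, and Oatp33Ea had 5 counts in replicate 1 and 8 in replicate 2 where 22.2 more would have come along, which speaks against this source there although the summed excess favoured it. In the Grh line the share of 3.16% (-1.90 to 8.49%), where zld needs 3.99%, leaves it open, and no biological explanation was tested.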
